A study of Mus musculus with 12 samples.

How the data were processed

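Livers of 12 mice were measured by enhanced reduced representation bisulfite sequencing, in which genomic DNA is cut with MspI and treated with bisulfite, so that unmethylated cytosines are read as T and methylated ones as C. The labels give 3 groups of 4 livers. Control livers came from parents with a floxed insulin receptor gene and no Cre, Father LIRKO livers from a LIRKO father and a control mother, and Mother LIRKO livers from a control father and a LIRKO mother. LIRKO mice lack the insulin receptor in liver, by Cre driven from the albumin promoter. The labels give neither the sex, the age nor the genotype of the offspring. CpGs on chromosome Y were read in each liver, 756 in Father LIRKO 3 and 1097 to 1234 in the others, which points to males in all 3 groups. No paired analysis was possible because the labels pair no livers across groups. Litter, sire and dam entered no test, and the 4 livers of a group were treated as independent animals. A litter or breeding pair shared within a group could not be told apart from the parental genotype. Replicates were numbered within each group in the order of the sample records.

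Per the labels, the submitters demultiplexed reads with BCL2FASTQ 2.17, trimmed adapters with FLEXBAR, aligned reads with Bismark in directional mode to mm10 and kept reads that aligned uniquely. Per the labels, a position was deposited only where it had at least 10 reads of sufficient base quality. The deposited files hold each strand on its own line, in 3 files per liver (36 files) for cytosines in CpG, CHG and CHH contexts. The coverage column is a count of reads at each cytosine, per the file headers. The freqC and freqT columns are the percent of those reads that kept C (methylated) or read T (unmethylated), per the file headers. Nothing in the deposited files records any other normalization. Depth ranged from 91434969 to 117660191 CpG calls per liver. PCR copies cannot be told from separate molecules without molecular identifiers, so read depth covers counting error only.

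Methylated and unmethylated read counts were recovered from coverage and percent, and the strands of each CpG were added. CpGs with at least 10 reads in all 12 livers were kept on the 19 autosomes, since the labels give no sex. CpGs above the 99.9th percentile of coverage in any liver were left out, which removed 4730 of 858376. The 853646 CpGs left were tested singly, in tiles of 1 kb with at least 3 such CpGs (74658 tiles, median 5 CpGs) and in windows at gene ends. The annotation, GRCm38.p6, which shares its coordinates with mm10, gave gene bounds but no strand, so transcription starts could not be placed. In place of promoters, each of 34614 coding or lncRNA genes was given the 2 windows of 1 kb on each side of its ends, and the window with the lower mean methylation over all livers was kept. At least 3 tested CpGs were required, which left 17161 windows (13254 of coding and 3907 of lncRNA genes, median 22 CpGs). A window is therefore not always at the promoter, and neighbouring genes can share CpGs.

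Differences were tested with a quasi-binomial model of read counts with 1 level per group, fitted to all 12 livers. Its dispersion was moderated across features with limma's squeezeVar and not allowed below 1. P-values were adjusted by Benjamini-Hochberg over the features of each contrast. A feature was called at an adjusted p under 0.05 and a difference of group means of at least 10 percentage points. Mean levels were compared by a two-sided exact permutation test over the 70 assignments of 8 livers, whose smallest possible p is 0.0286, adjusted over 9 tests. CHG and CHH levels are shares of methylated reads over autosomal positions. Values in the text are means ± SD over 4 livers, and differences are in percentage points.

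For named genes, the rule took called tiles and windows, and where fewer than 5 were called, the 10 with the smallest p stood in, described as not called. Of the features this rule named, 1 is not reported here. It also took up to 3 members of each gene list with the smallest p, and always Insr, Alb, Nnat and Gdf15. The naming of list members was narrowed after values were seen to the first member of each list and those past the threshold when adjusted over the list alone. There were 18 lists with 495 genes, of which 494 matched the annotation (2 by a synonym) and 350 had a window. Hnf4a, Grb10, Nnat and Cyp7b1 each stand in 2 lists. Lists were tested with limma's camera (preset correlation 0.01), beside camera with an estimated correlation and fry, and adjusted over 54 tests.

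Alternatives were a minimum of 20 reads, no coverage limit, single strands, CpGs covered in 3 of 4 livers per group, 500 bp tiles or windows, X included, other minimum differences, fits on only the 2 groups compared, limma on log2 ratios of methylated and unmethylated counts with 1 read added, edgeR's quasi-likelihood test on tiles, and each liver left out in turn. The groups, contrasts, tests, gene lists, naming rule and these alternatives were fixed before the data were examined. Chosen later were a binomial model without spread between livers, the removal of the 4 livers of largest excess spread, liver weights in limma (arrayWeights), an arcsine scale, both gene ends, a pooled contrast of both offspring groups with Control, and the leaving out of livers for lists and for the overlap. Counts at an unadjusted p under 0.05 and at least 10 points were used for splits of the livers, because no feature was called.

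Excess spread of a liver is the variance of its methylation around the mean of the other livers at CpGs of 30 to 70%, as a percent of the largest variance possible there. It includes read sampling, which at these depths is a small part. The model was tested on simulated data with the real depths and 200 changed features that lay near 50% methylation, 50 for each size of change. Father LIRKO livers were changed for the contrasts that hold them, and Mother LIRKO livers for Mother LIRKO minus Control. With Mother LIRKO livers changed instead, tiles in Father LIRKO minus Mother LIRKO were called in 8% of cases at 30 points and 40% at 40 points with each liver's own spread. With each liver's own spread, it called 26%, 26% and 32% of tiles changed by 40 points, and 4%, 2% and 4% of those changed by 30 points, for Father LIRKO minus Control, Mother LIRKO minus Control and Father LIRKO minus Mother LIRKO. For windows changed by 40 points the shares were 74%, 72% and 72%, and single CpGs were not recovered at any size. With the median spread of Mother LIRKO livers in all groups, the shares at 40 points were 84%, 94% and 92% of tiles. On tiles with each liver's own spread, limma called 0% at 40 points in Father LIRKO minus Control and 2% in Mother LIRKO minus Control, and edgeR called 0% in both. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16. Positions on X and Y were left out of the tests, and Nespas, a list gene, had no match in the annotation.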

Results

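The methylation of liver DNA was compared between 4 Control, 4 Father LIRKO and 4 Mother LIRKO offspring, to ask whether the loss of hepatic insulin signalling in a father or a mother, which gives that parent a metabolic syndrome, goes with a different hepatic methylome in the offspring. Each liver had between 91434969 (Control 3) and 117660191 (Mother LIRKO 3) CpG calls. Deposited CpG positions numbered 1353944 in Father LIRKO 3 and between 1562035 and 1742644 in the other 11 livers. Positions are on mm10. At the CpGs tested, the median depth per liver lay between 70 and 95 reads.

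Mean CpG methylation was near 30% in the 3 groups. It was 30.0% ± 0.0702 (SD, n = 4) in Control, 30.2% ± 0.264 in Father LIRKO and 30.1% ± 0.176 in Mother LIRKO livers. The differences were 0.207 points for Father LIRKO minus Control (exact permutation p = 0.257, adjusted 0.463), 0.111 for Mother LIRKO minus Control (exact p = 0.314, adjusted 0.471) and 0.0954 for Father LIRKO minus Mother LIRKO (exact p = 0.600, adjusted 0.771). As shares of methylated reads, which weight CpGs by depth, they were 0.802, 1.03 and -0.232 points, with a change of sign in the last. With 1 liver left out they ran from 0.122 (without Father LIRKO 3) to 0.286 (without Father LIRKO 4), from 0.0408 (without Mother LIRKO 3) to 0.184 (without Mother LIRKO 1) and from 0.0107 (without Father LIRKO 3) to 0.175 (without Father LIRKO 4). Methylation at CHG positions was 0.399% ± 0.160 in Control, 0.390% ± 0.102 in Father LIRKO and 0.228% ± 0.0468 in Mother LIRKO livers, and at CHH positions it was 0.427% ± 0.187, 0.417% ± 0.123 and 0.227% ± 0.0393. Mother LIRKO minus Control gave -0.171 points at CHG and -0.200 at CHH (exact p = 0.114, adjusted 0.257, for each). Father LIRKO minus Mother LIRKO gave 0.162 and 0.190 (exact p = 0.0571, adjusted 0.257, for each), and Father LIRKO minus Control -0.00889 and -0.0103 (exact p = 0.914, adjusted 0.914, for each). The last pair was positive without Control 3 (0.0548 at CHG, 0.0670 at CHH) or without Father LIRKO 4 (0.0356 and 0.0425). With positions above 20% left out, the others changed sign, to 0.00460 and 0.00709 for Mother LIRKO minus Control and to -0.0208 and -0.0244 for Father LIRKO minus Mother LIRKO. Over the 12 livers, the mean of the 21222 tiles under 5% methylation went with the CHH percent at positions read in all livers (Pearson r = 0.947, permutation p = 3e-05, adjusted 9e-05; Spearman rho = 0.909, permutation p = 0.00011, adjusted 0.00033; 3 relations computed). Without the 2 livers farthest from the median of the CHH percent, r was 0.881. These tiles had 1.31% ± 0.202 in Father LIRKO, 1.13% ± 0.0852 in Control and 1.06% ± 0.0250 in Mother LIRKO livers. The windows of Pparg, Fads1, Fads2, Eno1 and Ass1 lie in this range of methylation.

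**Figure D1:**
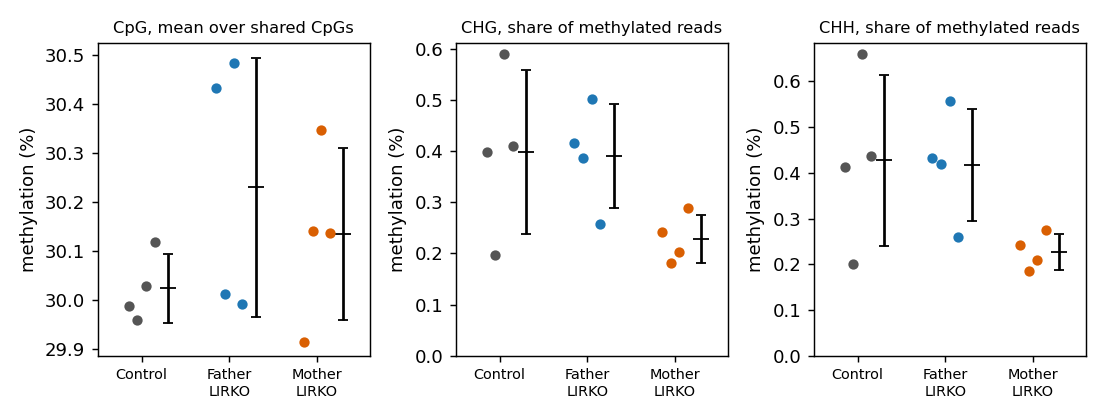
Methylation (percent) per liver, as dots, with the mean and SD of each group of 4 beside them: the mean over shared CpGs, on an axis that does not start at 0, and the share of methylated reads at CHG and CHH positions. The 4 Mother LIRKO livers lie between 0.181% and 0.288% at CHG, within the range of the Control livers at the upper end and just under it at the lower end.

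Insr, the gene of the insulin receptor that LIRKO parents lack in liver, was almost unmethylated at its gene-end window on chromosome 8 (bases 3278649 to 3280649, 25 CpGs). The window had 0.407% ± 0.536 in Control, 0.423% ± 0.338 in Father LIRKO and 0.134% ± 0.0704 in Mother LIRKO livers. Methylation there cannot show whether an offspring carried the deletion. Nnat, an imprinted gene for a membrane protein of the endoplasmic reticulum, was methylated at about the middle of the range, with 47.3% ± 6.55 in Control, 52.1% ± 12.6 in Father LIRKO and 49.3% ± 6.69 in Mother LIRKO livers (chromosome 2, bases 157561525 to 157563525, 11 CpGs). Gdf15, a stress-induced hormone of the TGF-beta superfamily, had 1.28% ± 0.351 in Control, 1.56% ± 0.639 in Father LIRKO and 2.18% ± 0.339 in Mother LIRKO livers (chromosome 8, bases 70628393 to 70630393, 35 CpGs). All 4 Mother LIRKO livers were above all 4 Control livers at Gdf15, an order that chance gives to 2.86% of windows in either direction, and the adjusted p was 0.997. Among the 3 tiles of Gdf15, 1 had an unadjusted p under 0.05, with an adjusted p of 1.00. Of the tiles within 5 kb of Insr (3), Nnat (4) and Alb (1), none had an unadjusted p under 0.05 in any contrast. Alb, the albumin gene, had 3 tested CpGs and no window.

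**Figure D2:**
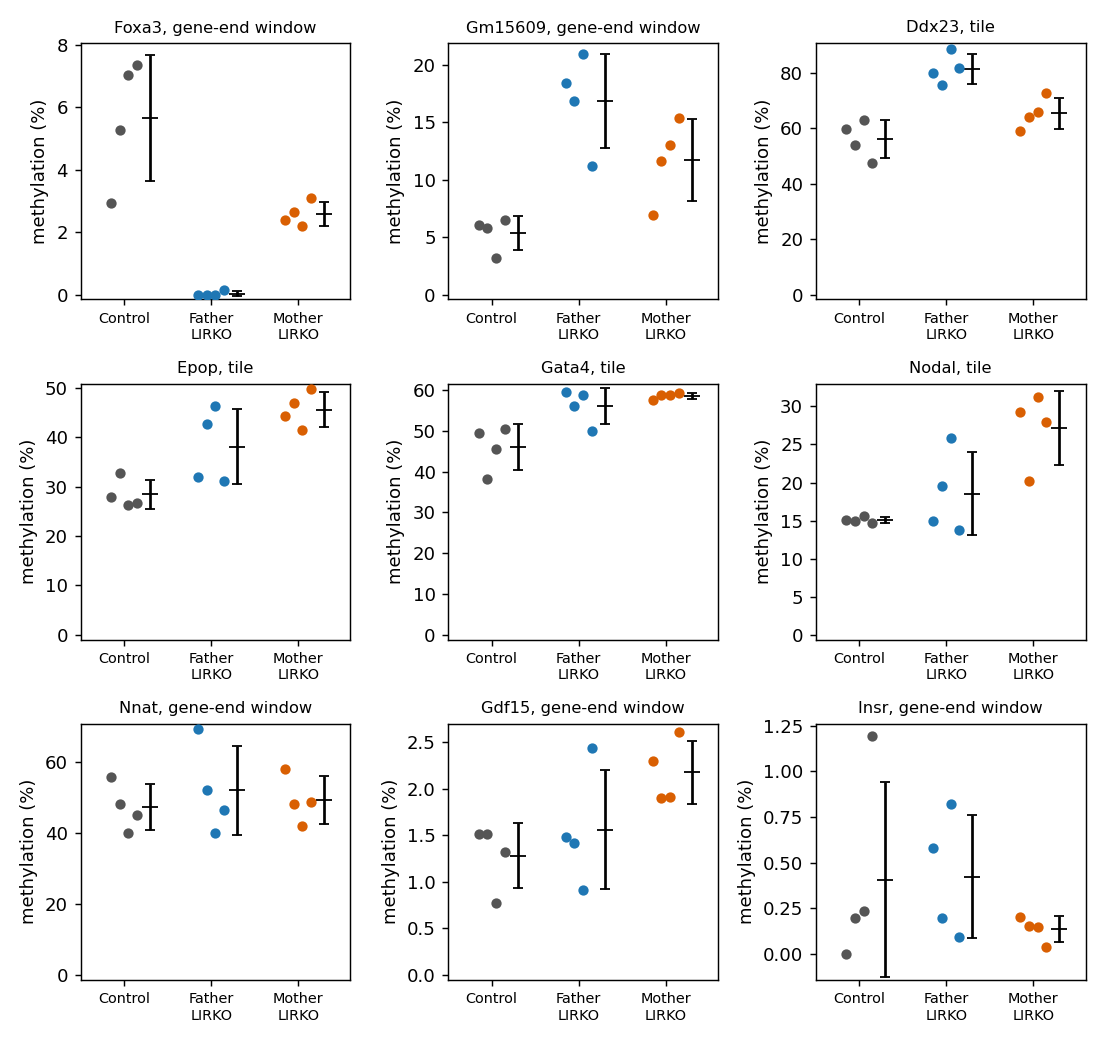
Methylation (percent) of 9 regions in each liver, as dots, with the mean and SD of each group of 4 beside them. At Foxa3 the Father LIRKO livers lie at or near 0 and the Control livers around 5.65%, and at Epop, Gata4 and Nodal the Mother LIRKO livers lie above all Control livers. None of these regions was called.

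Father LIRKO minus Control asks whether a LIRKO father goes with a different hepatic methylome. The window of Foxa3, a forkhead transcription factor of hepatocytes, held 8 CpGs (chromosome 7, bases 19012283 to 19014283). It had 0.0423% ± 0.0846 in Father LIRKO, 5.65% ± 2.01 in Control and 2.59% ± 0.394 in Mother LIRKO livers. At least 427 CpG calls per liver fell in it, where a read counts once for each CpG it covers. Single CpGs had as few as 21 reads. A tile inside Ddx23, which encodes a helicase of the spliceosome, had 81.4% ± 5.41 in Father LIRKO against 56.0% ± 6.81 in Control livers (chromosome 15, bases 98648001 to 98649000, 5 CpGs). A tile inside Mcph1, a gene of the DNA damage response, had 40.02% ± 5.17 against 71.3% ± 6.56 (chromosome 8, bases 18790001 to 18791000, 4 CpGs, at least 63 CpG calls per liver). The window of Gm15609, an RNA gene beside the synaptic scaffold gene Shank3, had 16.9% ± 4.12 against 5.38% ± 1.51 (chromosome 15, bases 89522750 to 89524750, 48 CpGs). A tile inside Shank3 (bases 89524001 to 89525000) had 23.0% ± 7.69 against 5.75% ± 3.26. It overlaps that window, so the 2 are not separate regions. None of these was called, with adjusted p between 0.256 and 0.435.

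Other tiles among those with the smallest p lay near Gm31763 (3.14% ± 2.13 in Father LIRKO against 13.4% ± 2.19 in Control livers), in Hspa12b of the heat shock protein 70 family (92.2% ± 2.96 against 76.7% ± 4.41), in Dact3, an antagonist of Wnt signalling (20.3% ± 1.80 against 14.2% ± 1.01), in Chn2 (0.295% against 1.86%) and in Sptbn4 (2.93% against 5.87%). The groups overlapped in none of the tiles named here, an order that chance gives to 2.86% of tiles, but the tiles were picked for their small p. Among windows, Pygm, the muscle form of glycogen phosphorylase, had 33.7% ± 2.24 against 23.5% ± 3.56. Parn, a poly(A) ribonuclease, had 3.33% ± 0.602 against 7.31% ± 1.11, and Pcyt2, an enzyme of phosphatidylethanolamine synthesis, 12.9% ± 1.54 against 17.5% ± 1.13. Golga1, Bsn, C2cd5, Camta1 and 9230110K08Rik were each under 2.4% in both groups and higher in Father LIRKO livers. The windows of Camta1 (bases 151860768 to 151862768) and 9230110K08Rik (bases 151860744 to 151862744) nearly coincide.

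Gene lists were compared by their windows. Adjustment over a list alone was repeated over 18 lists and 3 contrasts with no further correction. It also rests on p-values that ran small in simulated windows without a group difference, as given further below. How many members would pass it without any difference was not computed. Of 9 measured hepatocyte markers, 3 were past the threshold when adjusted over the list alone and 0 over all windows. These were Foxa3 (0.000353 adjusted over the list alone), Ass1 of the urea cycle (1.56% ± 1.56 in Father LIRKO against 0.255% ± 0.0507 in Control, 0.0468) and Foxa1 (11.8% ± 3.49 against 18.9% ± 6.05, 0.0468). Of 28 genes of fatty acid and triglyceride synthesis, 4 were past it when adjusted over the list alone and 0 over all windows, among them Pparg, a nuclear receptor of lipid storage (2.29% ± 1.74 against 0.4503% ± 0.353), and the desaturases Fads2 (1.42% ± 0.901 against 0.411% ± 0.203) and Fads1 (1.65% ± 1.84 against 0.211% ± 0.180), each at 0.0447. Of 34 imprinted genes, 4 were past it over the list alone and 0 over all windows. Peg3 and Usp29, which share the CpGs of their window, had 48.9% ± 13.4 against 28.9% ± 8.90, and Mest had 28.7% ± 5.42 against 43.7% ± 7.99 (0.0487 each). Peg3 and Usp29 are 1 region that entered the adjustment, and the total given further below, as 2 members. The 4 are therefore not 4 separate regions. The list was not adjusted with that region counted once, so whether any member would then pass is not known. Eno1, a glycolytic enzyme, was the 1 of 18 genes of gluconeogenesis and glycolysis (1.69% ± 1.21 against 0.103% ± 0.146, 0.00807). Pdgfra, a growth factor receptor of stellate cells, was the 1 of 13 stellate cell and fibroblast markers (0.173% ± 0.235 against 10.97% ± 5.75, 0.0256). Over all windows the counts for the last 2 lists were 0.

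The other 13 lists had 0 members past the threshold over the list alone or over all windows. Their first members were Jak2 of cytokine signalling (0.629% against 0.122%, over the list alone 0.0696; inflammation and acute phase, 15 windows), Skil (0.565% against 0.141%, 0.103; TGF-beta and BMP signalling, 38), Cux2 (1.21% against 2.30%, 0.111; sex-biased liver genes, 8), Eng (74.8% ± 16.5 against 55.1% ± 3.01, 0.174; endothelial cell markers, 9) and Dvl1 (0.670% against 0.139%, 0.181; Wnt signalling, 36). Acadm (2.28% against 0.698%, 0.200; fatty acid oxidation and ketogenesis, 19), Cldn4 (40.4% ± 7.89 against 25.9% ± 8.08, 0.237; cholangiocyte markers, 14), Mmp2 (5.24% against 3.03%, 0.337; extracellular matrix and fibrosis, 20) and Mbd2 (0.463% against 0.155%, 0.415; DNA methylation and one-carbon metabolism, 25) came next. The rest were Gsk3a (1.15% against 0.294%, 0.422; insulin signalling, 24), Lss (11.1% ± 3.98 against 6.83% ± 1.14, 0.448; cholesterol, lipoprotein and bile acid metabolism, 20), Nfil3 (1.71% against 0%, 0.472; circadian clock, 16) and Cd79b (76.0% against 79.9%, 0.688; Kupffer cell and leukocyte markers, 7). Averaged over the windows of each cell type, hepatocyte markers had 4.35% ± 0.215 in Father LIRKO against 6.28% ± 1.32 in Control livers (-1.93 points, exact permutation p = 0.0286), and cholangiocyte markers 6.86% ± 0.6995 against 5.56% ± 0.583 (exact p = 0.0286), each with an adjusted p of 0.107 over 15 tests. Stellate markers differed by -2.73 (exact p = 0.0857), endothelial markers by 4.08 (exact p = 0.0857) and Kupffer cell and leukocyte markers by 0.490 (exact p = 0.714). Single windows weigh heavily in these means, with differences of 14.5 points at Cldn4, 19.7 at Eng, -7.03 at Foxa1, -5.61 at Foxa3 and -10.8 at Pdgfra. By camera the cholangiocyte and endothelial lists, neither past the threshold, pointed the other way, downwards in Father LIRKO livers. None of the 54 list tests of the 3 contrasts passed by camera. The smallest adjusted p, 0.113 for stellate markers in Father LIRKO minus Control, was p = 0.946 with an estimated correlation and 0.684 by fry. With livers left out, camera passed 1 list without Control 4 and 2 without Father LIRKO 4. For changes in either direction, fry gave an adjusted p of 1.2e-06 for hepatocyte markers here and 1.5e-06 in Father LIRKO minus Mother LIRKO. Both results share Foxa3. With windows of 500 bp on each side, where 7 of the markers were measured, fry gave 0.865 and 0.909. The Foxa3 CpGs (bases 19012295 to 19012471) lie more than 500 bp outside the gene end at base 19013283. The narrower windows therefore left these CpGs out and did not test them again.

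The quasi-binomial test called 0 CpGs, 0 tiles and 0 windows in Father LIRKO minus Control. An unadjusted p under 0.05 was found at 90658 CpGs (10.6%), 7162 tiles (9.59%) and 1841 windows (10.7%), of which 32399, 2547 and 179 differed by at least 10 points. Tiles with an unadjusted p under 0.05 numbered 5255 by limma, 3745 by limma with liver weights and 3632 by edgeR, and windows 1202 by limma and 913 with weights, with 0 called by each. Past limma's adjusted threshold, with under 10 points of difference, were the tile of Foxa3 (log2 ratio -5.01, SE 0.46, adjusted p = 0.0101) and its window (-4.96, SE 0.46, adjusted p = 0.00242). Unmethylated livers leave such log2 values dependent on the 1 read added. Without Father LIRKO 4, the window of Gm15609 was called (18.8% against 5.38%). Members past the threshold over the list alone numbered 13 in all, but 2 without Control 2, 3 without Mother LIRKO 1 or Mother LIRKO 4, 4 without Control 1 or Control 3, 5 without Mother LIRKO 2, 6 without Mother LIRKO 3, 7 without Control 4 and 8 without Father LIRKO 2, and fatty acid synthesis and stellate markers had 0 without Father LIRKO 3. Foxa3 and Eno1 stayed past it with each of the 12 livers left out. Father LIRKO 3 stood apart at partly methylated CpGs, with an excess spread of 67.8% against 7.36 to 23.7% in the other 11 livers, and simulated windows with such uneven spread and no group difference had a p under 0.05 in 10.5% of cases, against 8.02% with the same spread in all livers.

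**Figure D3:**
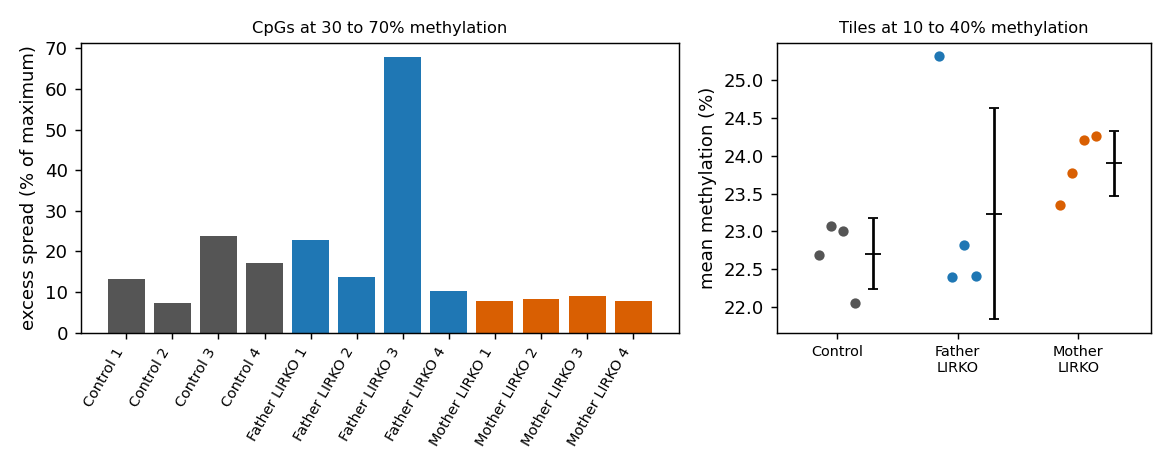
Left, excess spread of each liver at the 63617 CpGs of 30 to 70% methylation, in percent of the maximum, with bars from 0. Right, mean methylation (percent) of the 5969 tiles of 10 to 40%, per liver as dots with the mean and SD of each group of 4, on an axis that does not start at 0. Father LIRKO 3 has 67.8% excess spread, and the 4 Mother LIRKO livers (23.3 to 24.3%) lie above the 4 Control livers (22.05 to 23.1%).

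Mother LIRKO minus Control asks the same of a LIRKO mother. A tile of Epop, which encodes a partner of the Polycomb complex PRC2, had 45.6% ± 3.53 in Mother LIRKO against 28.4% ± 2.98 in Control livers (chromosome 11, bases 97627001 to 97628000, 13 CpGs). Gata4, an endoderm and heart transcription factor, had 58.6% ± 0.698 against 46.0% ± 5.60 (chromosome 14, bases 63240001 to 63241000, 29 CpGs). Nodal, a TGF-beta ligand of embryonic patterning, had 27.2% ± 4.86 against 15.1% ± 0.394 (chromosome 10, bases 61418001 to 61419000, 20 CpGs). Foxj1, a regulator of cilia, had 37.8% ± 2.00 against 25.1% ± 5.87 at its tile. None was called, with an adjusted p of 1.00 for each tile.

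Tiles with an unadjusted p under 0.05 and at least 10 points were higher in Mother LIRKO livers in 520 cases and lower in 294. Among tiles under 5% methylation, 259 with such a p were higher and 556 lower, at any size of difference. Of the 10 tiles with the smallest p, 9 had the higher mean in Mother LIRKO livers. The others of these were Elfn2 (62.8% ± 5.67 against 44.3% ± 5.55), Rtn4rl2, a Nogo receptor relative (38.6% ± 3.95 against 23.9% ± 1.72), Ltb4r2, a leukotriene receptor (24.5% ± 1.42 against 17.5% ± 1.42), the homeobox gene Six4 (13.5% ± 0.595 against 5.64% ± 2.36) and Gata6 (10.0% ± 1.27 against 5.92% ± 1.23). Nid2, a basement membrane nidogen, had 0.236% ± 0.185 against 2.85% ± 1.097. Among windows, Fut4, a fucosyltransferase, had 8.84% ± 1.03 against 3.43% ± 1.51, and Dnajc12, a cochaperone, 12% ± 2.51 against 3.68% ± 1.69. Igfbp4, a binding protein of insulin-like growth factors, had 11.1% ± 0.990 against 26.0% ± 9.14. Foxj1 (16.3% ± 1.45 against 9.79% ± 3.75), Prxl2b (16.8% ± 1.44 against 9.32% ± 2.92), Gm42094 (91.8% ± 0.476 against 82.2% ± 4.38) and Slc47a1, an organic cation exporter (3.15% ± 0.837 against 0.522% ± 0.839), had higher means in Mother LIRKO livers. Bag6 (0.258% against 1.599%) and Mageb3 (0.0300% against 0.793%) had lower ones. The adjusted p of each window was 0.997.

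None of the 18 lists had a member past the threshold in Mother LIRKO minus Control, over all windows or when adjusted over the list alone, and members with an unadjusted p under 0.05 numbered 0 to 2 per list. The smallest over the list alone was 0.117 for Mttp, which loads lipid onto lipoproteins (0.141% ± 0.119 against 0.702% ± 0.287). Fah, an enzyme of tyrosine breakdown, led the hepatocyte markers (0.566% against 1.17%, 0.221), Rheb the insulin signalling genes (0.147% against 0.601%, 0.312) and Rela the inflammation genes (1.598% against 2.37%, 0.393). H19 led the imprinted genes, with 31.1% ± 10.0 against 55.8% ± 28.3 (0.583). Axin2 (50.0% ± 5.91 against 67.9% ± 18.3, 0.650), Pfkl (1.18% against 2.44%, 0.600), Nog (0.880% against 1.34%, 0.601), Col14a1 (1.17% against 4.18%, 0.569) and Stat5b (17.3% against 13.1%, 0.704) led their lists of Wnt signalling, gluconeogenesis and glycolysis, TGF-beta and BMP signalling, stellate cell and fibroblast markers and sex-biased liver genes. In the other lists the leading members were Nr1d1 (0.762), Col18a1 (0.775), Eng (0.814), Mtrr (0.866), Cd4 (0.898), Abhd5 (0.908), Plin2 (0.951) and Spint2 (0.961). Hepatocyte marker windows averaged 5.87% ± 0.286 against 6.28% ± 1.32 (exact permutation p = 0.629). Kupffer cell and leukocyte markers differed by 1.07 points, endothelial markers by -0.798, stellate markers by -0.158 and cholangiocyte markers by 0.468 (exact p between 0.343 and 0.771).

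The quasi-binomial test called 0 CpGs, 0 tiles and 0 windows in Mother LIRKO minus Control. An unadjusted p under 0.05 was found at 60865 CpGs (7.13%), 2555 tiles (3.42%) and 663 windows (3.86%), of which 12927, 814 and 73 differed by at least 10 points. By limma 1860 tiles and 552 windows had an unadjusted p under 0.05, with liver weights 3958 and 959, and by edgeR 1408 tiles, with 0 called by each. With weights, limma put 1 window under 10 points of difference past the adjusted threshold, Ankrd45 (0% against 2.18% ± 0.738, adjusted p = 0.0222). Without Father LIRKO 3, which enters through the shared dispersion, 4383 tiles and 1108 windows had an unadjusted p under 0.05 and 1 tile inside Agap3 was called (35.7% against 24.5%), and without the 4 livers of largest excess spread 2 tiles were called, at Agap3 and near Rbakdn. Without Control 2, the windows of Fut4 and Foxj1 were past the adjusted threshold, with differences of 6.14 and 8.38 points, too small to be called.

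Father LIRKO minus Mother LIRKO compares offspring of a LIRKO father with those of a LIRKO mother. A tile inside Diras1, a small GTPase of the Ras family, had 41.3% ± 4.09 in Father LIRKO against 57.9% ± 3.58 in Mother LIRKO livers (chromosome 10, bases 81022001 to 81023000, 12 CpGs). Rasa2, a Ras GTPase-activating protein, had 49.6% ± 2.71 against 66.0% ± 6.03 at a tile within 5 kb, and Cldn4, a tight junction claudin, 51.3% ± 5.59 against 66.5% ± 3.49. The window of Pygm, the muscle glycogen phosphorylase, had 33.7% ± 2.24 against 24.5% ± 1.66. None was called, with an adjusted p of 0.515 for each tile and 0.323 for each window named here.

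The other tiles lay in Evpl (44.8% ± 10.2 in Father LIRKO against 66.1% ± 4.67 in Mother LIRKO), Nxph4 (13.7% ± 3.48 against 23.6% ± 1.52), Miga1, a mitochondrial fusion gene (82.5% ± 7.82 against 94.7% ± 1.23), Oxct2a, a ketone body enzyme (0.739% ± 1.48 against 8.99% ± 4.30), and Zfp11 (3.88% ± 1.77 against 0.305% ± 0.335), and between genes nearest to Ebpl (13.3% ± 9.50 against 44.5% ± 10.6) and Gorasp2 (38.6% ± 12.8 against 15.9% ± 7.12). Dpp3, a dipeptidyl peptidase, and Bbs1 of the BBSome share a window with 9.58% ± 2.48 against 17.6% ± 2.87. The windows of Med23 of the Mediator complex (1.58% against 0.288%), Wdr93 and Pex11a (1.07% against 0.0440%, the same CpGs), Tinf2 (1.41% against 0.206%), Mrm1 (1.596% against 0.170%), Ddx39b (0.918% against 0.128%) and Sp4 (1.12% against 0.0965%) were each nearly unmethylated in both groups.

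Among gene lists, Foxa3 was the 1 of 9 hepatocyte markers past the threshold when adjusted over the list alone (0.0104), Pparg the 1 of 28 genes of fatty acid and triglyceride synthesis (2.29% ± 1.74 against 0.472% ± 0.233, 0.0384) and Eno1 (0.0316) and Pfkl (3.00% ± 1.603 against 1.18% ± 0.454, 0.0462) the 2 of 18 genes of gluconeogenesis and glycolysis. Of 8 sex-biased liver genes, 2 were past it, Cux2 (1.21% ± 0.560 against 2.50% ± 0.328) and Ghr, the growth hormone receptor (2.45% ± 1.54 against 6.66% ± 2.09), each at 0.0386. Eng, a TGF-beta coreceptor of endothelium, was the 1 of 9 endothelial markers (74.8% ± 16.5 against 48.2% ± 6.13, 0.0114). Over all windows these lists had 0. The other 13 lists had 0 by either count. Their first members were Skil (0.565% against 0.122%, over the list alone 0.0535), Acadm (2.28% against 0.458%, 0.0538), Ptpn1, a phosphatase that acts on the insulin receptor (30.7% ± 5.37 against 45.7% ± 2.72, 0.0588), Jak2 (0.629% against 0.169%, 0.0976), Uhrf1 (0.762% against 0.107%, 0.127) and the imprinted Peg13 (32.6% ± 6.30 against 43.9% ± 3.91, 0.137). For the rest, Lgr5 had 0.201, Mttp 0.281, Pdgfra 0.347, Adgre1 0.429, Krt19 0.498, Per3 0.578 and Fn1 0.743. Of 38 TGF-beta and BMP genes, 9 had an unadjusted p under 0.05, all with the higher mean in Father LIRKO livers, as had 2017 of the 2378 tiles under 5% with such a p, and camera gave the list an adjusted p of 0.946. Endothelial marker windows averaged 27.3% ± 3.11 against 22.5% ± 1.19 and hepatocyte marker windows 4.35% ± 0.215 against 5.87% ± 0.286 (exact permutation p = 0.0286 each, adjusted 0.107). Stellate markers differed by -2.58 points (exact p = 0.0571), cholangiocyte markers by 0.825 (exact p = 0.171) and Kupffer cell and leukocyte markers by -0.576 (exact p = 0.857). Eng alone, with 26.6 points, made up most of the endothelial difference, and by camera the endothelial, cholangiocyte and Kupffer cell lists, none past the threshold, pointed the other way.

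The quasi-binomial test called 0 CpGs, 0 tiles and 0 windows in Father LIRKO minus Mother LIRKO. An unadjusted p under 0.05 was found at 91121 CpGs (10.7%), 6639 tiles (8.89%) and 2133 windows (12.4%), of which 27254 CpGs, 876 tiles with the higher and 1150 with the lower mean in Father LIRKO livers, and 158 windows differed by at least 10 points. By limma 4607 tiles and 1296 windows had an unadjusted p under 0.05, with liver weights 4423 and 1244, and by edgeR 3059 tiles, with 0 called by each. Past limma's adjusted threshold, with under 10 points of difference, were 2 windows, Foxa3 (log2 ratio -3.89, SE 0.46, adjusted p = 0.0341) and Golm1, which encodes a Golgi membrane protein (0% against 2.86% ± 1.53, adjusted p = 0.0449). Without the 4 livers of largest excess spread, the window of Brd3os was called (19.7% against 39.0%). Members past the threshold over the list alone numbered 7 in all, but 1 without Mother LIRKO 3, 2 without Mother LIRKO 1 or Mother LIRKO 4, 3 without Mother LIRKO 2 or Control 2, 13 without Father LIRKO 1 and 17 without Father LIRKO 4. Without Father LIRKO 3 the endothelial markers and fatty acid synthesis had 0, and Foxa3 stayed past it with each of the 12 livers left out.

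The overlap of Father LIRKO minus Control with Mother LIRKO minus Control asks whether both parents go with the same differences. No tile was called in both, or in either. At an unadjusted p under 0.05 and at least 10 points, 163 tiles were higher in both and 86 lower in both. Simulated groups without a difference, set against the same controls, gave a mean of 150 (at most 177 in 20 draws) and 107 (at most 123). Over tiles, which are not independent replicates, the differences had a correlation of 0.472, against 0.481 (0.473 to 0.489 in 50 draws) in the simulated groups. With the Control livers divided 2 and 2 between the contrasts, the correlation had a mean of -0.000684 over 6 assignments (-0.00629 to 0.00366). The covariance then had a mean of -0.024. With all Control livers shared, the measured correlation lay just under the range of the simulated groups, whose differences share nothing but the Control livers. The covariance of the differences with shared Control livers was 10.08 in the data, against a mean of 11.74 (lowest 11.43) in the simulated groups. Tiles at the same threshold numbered 2547 in Father LIRKO minus Control and 814 in Mother LIRKO minus Control, against simulated means of 2846 and 835. The simulated groups thus varied more than the data. Set against them, the counts and the correlation of 0.472 cannot decide whether both parents go with the same differences. The division of the Control livers answers a narrower question. Over all tiles, no correlation was left once no Control liver was shared. It does not test single tiles.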

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

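Chosen only after the result was seen were the conversion test for Father LIRKO 3, all tests of the partly methylated tiles in Mother LIRKO livers, the means over cell-type windows, the splits of simulated livers, and the simulated and unmethylated shares of tiles given for the counts of the 2 offspring comparisons.

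Father LIRKO 3 stood apart from the other 11 livers at partly methylated CpGs, with an excess spread of 67.8%, against 23.7% in Control 3, the next highest, and its weight among tiles in limma was 0.145, against 0.590 to 1.87. A library amplified from few template molecules would make the strands of a CpG, which are read from separate molecules, disagree. The mean absolute difference between strands at CpGs of 30 to 70% was 43.1 points in Father LIRKO 3, above the 33.1 points of the highest other liver, so few templates may be the source. Father LIRKO 3 also had the highest CHH percent at positions read in all livers (0.420%, next 0.311%). As the whole cause, incomplete conversion is argued against, since it can only add methylation, and 24.9% of CpGs with a mean of 30 to 70% in the other livers were at 10% or less in Father LIRKO 3, against 6.54% in the highest other liver. Tissue grown from few cells would give both strands of a CpG the same state, with opposite strands no more common than in other livers. This was not met, as opposite strands were found at 18.2% of these CpGs, above the 7.16% of the highest other liver. The correlation between strands, 0.0388, was the lowest of any liver. The bound for arguing against such tissue, 5 times the 7.16%, was not reached. Only 38.2% of these CpGs in Father LIRKO 3 had both strands at an extreme of methylation, and opposite strands can occur only among them. The bound would have needed nearly all of them, so it cannot decide the question, and such tissue stays open as a part of the cause. A difference that comes from the parents stays open as well and was not tested.

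Tiles of 10 to 40% methylation had a higher mean in Mother LIRKO livers (23.9% ± 0.430) than in Control livers (22.7% ± 0.467), with all 4 above all 4 (1.20 points, exact permutation p = 0.0286, the smallest possible, adjusted 0.0857 over 3 contrasts). This band was chosen after 7 classes of tiles had been tested, in which the classes of 10 to 20% and 20 to 40% had an adjusted p of 0.200 over 21 tests. In Father LIRKO livers the mean was 23.2% ± 1.40 (exact p = 0.686 against Control). Methylated reads at CHH positions differed between Mother LIRKO and Control livers by -0.0497 points over positions read in all livers and by 0.00709 over positions of at most 20%. Incomplete conversion is argued against by size rather than by this sign, since the highest CHH percent of a Mother LIRKO liver was 0.274%, under the 1.20 points of difference. Few template molecules in the Control libraries stay open, as the mean of these tiles had a Spearman correlation of -0.336 with excess spread over the 12 livers (permutation p = 0.288; Pearson r = -0.122, permutation p = 0.728, and 0.153 without Control 3 and Father LIRKO 3; 3 relations, adjusted 0.288 and 0.728). Fewer hepatocytes in Mother LIRKO livers stay open too, since their hepatocyte marker windows differed from Control by -0.414 points (exact p = 0.629). A difference that comes from a LIRKO mother was not tested apart from these.

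Splits of the 8 livers of each contrast, 35 in number, were counted at an unadjusted p under 0.05 and at least 10 points, since no feature was called. In Father LIRKO minus Control, 11 splits gave as many CpGs (32399 in the real split, 34619 in the highest other), 11 as many tiles (2547 and 2714) and 28 as many windows (179 and 218), so chance cannot be excluded. In Mother LIRKO minus Control, 1 split, the real one, gave as many CpGs (12927, highest other 12486), tiles (814 and 723) and windows (73 and 67). In Father LIRKO minus Mother LIRKO, 1 split, again the real one, gave as many CpGs (27254, highest other 25624), tiles (876 higher and 1150 lower, highest other 1878 in all) and windows (158 and 146). These counts do not exclude chance where livers differ in spread. Livers were simulated in 5 draws with each liver's own spread and no group difference. The real split held 809 to 852 tiles for Mother LIRKO minus Control (814 in the data) and was the highest of 35 in 1 draw. For Father LIRKO minus Mother LIRKO it held 2118 to 2216 tiles (above the number in the data in each draw) and was the highest in 2. Simulated splits held more tiles than those of the data, however. Their medians were 771 to 799 for Mother LIRKO minus Control, above the 723 of the highest other split in the data. For Father LIRKO minus Mother LIRKO they were 1985 to 2014, above 1878. The draws therefore bear on the rank of the real split alone, and do not show that uneven spread gives its lead.

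Tiles with an unadjusted p under 0.05 made up 9.59% in Father LIRKO minus Control and 3.42% in Mother LIRKO minus Control. Without Father LIRKO 3 the shares were 8.10% and 5.87%. The first exceeded the bound of 7% set beforehand for arguing against this liver as the only source. That bound cannot decide the question, because simulated livers without a difference had shares near or above it. None were simulated without Father LIRKO 3. Simulated livers with their own spread and no group difference had 9.54% and 5.22%, those with the same spread in all livers 6.83% and 6.80%, and tiles under 5% methylation held 32.3% of the small p in Father LIRKO minus Control, against 28.4% of all tiles.

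Single livers lay far from the other 3 of their group in 25 of 342 groups of values, where chance gives 1 in 20, or 17.1, and Father LIRKO 4 held the most with 5. Among tiles these were Gm31763 in Mother LIRKO 3 (6.79%, others 10.4 to 11.1%), Foxa3 in Father LIRKO 4 (0.154%, others 0%), Mcph1 in Father LIRKO 1 (47.8%, others 37.0 to 38.1%), Chn2 in Mother LIRKO 4 (1.06%, others 0.637 to 0.654%) and Shank3 in Mother LIRKO 4 (20.0%, others 7.88 to 9.34%). Further tiles were Ltb4r2 (18.5%, others 23.7 to 24.4%) and Zfp11 (6.54%, others 2.94 to 3.11%) in Father LIRKO 4, and Oxct2a in Father LIRKO 2 (2.95%, others 0%) and in Mother LIRKO 1 (15.4%, others 6.46 to 7.48%). Among windows, Control 2 was apart at Pygm (28.9%, others 21.7 to 21.8%), Foxj1 (15.4%, others 7.57 to 8.44%) and Slc47a1 (1.78%, others at most 0.144%), and Father LIRKO 4 at Foxa3 (0.169%, others 0%) and Mageb3 (0.608%, others at most 0.0998%). Father LIRKO 3 was apart at Mbd2 (1.06%, others at most 0.310%), Lss (17.0%, others 8.65 to 9.40%) and Fads1 (4.39%, others at most 1.01%), and Father LIRKO 2 at Axin2 (51.6%, others 62.3 to 64.3%). Control 4 was apart at Sp4 (0.655%, others at most 0.161%) and Abhd5 (1.25%, others at most 0.309%), and Control 3 at Plin2 (15.1%, others at most 1.13%). Mother LIRKO 2 was apart at Parn (6.53%, others 4.09 to 4.44%), Plin2 (0.241%, others 0%) and Fah (0.876%, others at most 0.487%), and Mother LIRKO 4 at Dnajc12 (8.24%, others 13.1 to 13.5%).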

How the results depend on the processing

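Chosen only after the result was seen were the binomial model, the removal of 4 livers, liver weights, the arcsine scale, both gene ends, the pooled contrast, and livers left out for lists and overlap. The 45 counts under planned settings other than a liver left out stayed at 0, as did 106 of 108 with 1 liver left out. Of 132 alternatives for mean levels 121 kept their direction, and 130 of 130 named features moved by less than 1 SD.

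Father LIRKO minus Mother LIRKO in mean CpG methylation was -0.232 as the share of methylated reads. Father LIRKO minus Control was 0.0349 at CHG and 0.0440 at CHH over positions read in all 12 livers. With positions above 20% left out, Mother LIRKO minus Control was 0.00460 and 0.00709, and Father LIRKO minus Mother LIRKO -0.0208 and -0.0244. This limit was applied in each liver apart. Father LIRKO 3, with the largest excess spread, went from 0.557% to 0.0820% at CHH, the lowest of any liver. The changes of sign therefore cannot tell highly methylated positions from the spread of single livers. With 1 liver left out, Father LIRKO minus Control ran from -0.0760 to 0.0548 at CHG and from -0.0857 to 0.0670 at CHH, and the cause was not tested.

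Without a term for spread between livers, the binomial model called 99576, 59078 and 88502 CpGs, 5460, 2505 and 4517 tiles and 411, 215 and 343 windows for Father LIRKO minus Control, Mother LIRKO minus Control and Father LIRKO minus Mother LIRKO, because it counts reads as independent. Without the 4 livers of largest excess spread (Father LIRKO 3, Father LIRKO 1, Control 3 and Control 4), which leaves 2 against 2 in Father LIRKO minus Control, 3 tiles were called there (Agap3, Arhgap33 and Rab44), 2 in Mother LIRKO minus Control (Agap3 and 1 near Rbakdn), and 1 window in Father LIRKO minus Mother LIRKO (Brd3os). With 1 liver left out, called tiles in Mother LIRKO minus Control ran from 0 to 1 (Agap3, without Father LIRKO 3), called windows in Father LIRKO minus Control from 0 to 1 (Gm15609, without Father LIRKO 4), and gene lists past camera from 0 to 2 (1 without Control 4, 2 without Father LIRKO 4). The correlation of the 2 offspring comparisons ran from 0.405 to 0.579, and had a mean of -0.000684 over 6 assignments with Control livers divided 2 and 2. In the self-test at the real depths, tiles changed by 30 points were called in 2% to 8% of cases with each liver's own spread, over the contrasts and with either offspring group changed, and in 32% to 70% with the median spread of Mother LIRKO livers in all. Depth was not varied.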

Other observations

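Chosen only after the result was seen were the tests of a strain variant and of methylation in liver cells, and the pooled contrast. At non-CpG cytosines, 288 positions were above 50% in at least 8 livers, and 203 of them lay on chromosome 8 (bases 3398824 to 122335693), which held 70.5% of them against 5.86% of covered positions, a ratio of 12.02. A sequence variant of the mouse strain against the reference may be the source, since variants come in blocks, and 142 of the 203 lay below 50 Mb and 57 between 80 and 97 Mb. Methylation of non-CpG cytosines in liver cells is argued against by the same ratio of 12.02. Local failure of conversion is argued against by the other non-CpG cytosines within 10 bp, with a median of 0% (179 positions with such neighbours, highest 1.66%). Insr, floxed in all groups, lies on the same chromosome at bases 3150922 to 3279649, and a segment linked to it is a hypothesis that was not tested. The median over the 203 positions was 96.3% in Control, 96.9% in Father LIRKO and 90.8% in Mother LIRKO livers. Between 82 and 90 Mb, Control 3 and Father LIRKO 2 had 0 of these positions read, against 13 to 22 in the other 10 livers.

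Methylation of the Foxa3 window lay at different CpGs in different Control livers, at 6 of its 8 CpGs in all. In Control 4 it was 33.3% at bases 19012453 and 19012464 and 34.3% at base 19012471. Control 2 had 22.9% at base 19012453, 10.1% at base 19012466 and 2.79% at base 19012384, and Control 3 had 20.8% at base 19012384 and 0% at the other CpGs. Control 1 had 13.2% at base 19012334, 6.25% at bases 19012453 and 19012464 and 1.04% at base 19012471. Mother LIRKO livers had 8.49 to 12.1% at base 19012453 and at most 7.14% at the other CpGs. In Father LIRKO livers 1 CpG was above 0, with 1.67% at base 19012295 in Father LIRKO 4.

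Both offspring groups pooled against Control gave 2947 tiles with an unadjusted p under 0.05 by limma and 3660 with liver weights, with 0 called by either.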
